A study of Mus musculus with 745 samples.

How the data were processed

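The samples were single primary brain endothelial cells of 3-month-old mice, dissociated with a neural tissue kit and isolated by FACS, whose gate markers are not given in the sources used here. Each of the 745 samples was 1 cell. The title of each cell began with m1, followed by Young1, Young2 or AY_Y3. It ended in a letter and a number, read here as a plate position. The names Young1, Young2 and AY_Y3 divided the cells into 3 sets of 225, 258 and 262 cells. The labels do not say whether a set is a mouse, a pool of mice or a plate, nor what m1, shared by the sets, or AY stands for. With the set as a block, p-values measure only how class differences vary over these sets, and that spread may be technical.

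The values were whole-number counts of reads per gene, as deposited, with no normalization: 20607 gene symbols by 745 cells, of which 708 symbols had no count in any cell. Bowtie 0.12.2 and the genome builds mm8 and mm10 were named in the submitters' processing notes, without a role for either build. The counting tool, the annotation and the use of strand are not given in the sources used here, and no coordinates are printed for that reason. Genes that share reads with close copies are uncertain, among them the ribosomal protein genes, mitochondrial genes with nuclear copies, the H2-Q genes, Ifit3 and Ifit3b, Hspa1a and Hspa1b, and Amd1 and its pseudogene. Without strand, reads of overlapping or antisense genes cannot be told apart. The counts carried no molecular identifiers: reads are not independent molecules, and every interval and floor given here covers counting error only. Symbols of some list members were not among those in the table (Lyve1, Cd74, H2-Aa, Ccl2 and Lrp2, for example), and Plvap, a gene of caveolar diaphragms, did not pass the filter on low counts.

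Cells needed at least 500 genes with a count and at least 50000 counts, and all 745 met both. Counts per cell ran from 52819 to 2421434, and no cell lay below the depth of 50000 counts used for thinning. Cells were clustered on the 2000 most variable genes (log counts per 10000, 10 principal components, 15 neighbours, Leiden resolution 1) with leidenalg 0.10.2 and scikit-learn 1.9.0, under Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Clusters named for another cell type were left out. The remaining endothelial cells were clustered again on 41 segment markers alone, each scaled within its set. The markers, the gene lists, the tests, the rule for named genes and all but 2 of the alternatives were fixed before the data were examined. The rule that turned markers into names was chosen after the data were seen. A marker counted as raised at 1.25 times its mean CPM in the other cells or more and with a count in at least 25% of the cluster's cells. A name needed 3 raised markers and the largest share of a class's markers raised, and no other class could have more markers among the cluster's top 10 genes by fold. No doublet caller was run. Doublets were treated by leaving out clusters named for other types and, as an alternative, the cells with the most mural transcripts (over 10 CPM on pericyte and smooth muscle markers and in the top 5% of their set).

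Cells are not replicates. Raw counts were summed per set and class, which gave 9 sums of 39 to 78 cells and 21544334 to 57936594 counts. edgeR 4.0.16 (R 4.3.3) fitted its quasi-likelihood model to all 9 sums with TMM library sizes and the set as a block, which left 4 residual degrees of freedom, and tested each contrast with Benjamini-Hochberg adjustment at a threshold of 0.05. The set was a block because all classes came from each set. Genes passed edgeR's default filter on low counts and had a count in at least 5% of the cells entering, and the segment markers were left out, so that no tested gene had been used to define a class. This left 9302 genes, of which 105 passed between arterial-like and capillary-like cells, 0 between venous-like and capillary-like and 171 between arterial-like and venous-like cells; shares of tested genes are given as percentages elsewhere. The classes were nonetheless drawn from the same cells, and genes that vary with the markers are expected to differ between them. CPM are given as the mean ± SD of the 3 sets, and log2 fold changes as the fitted value ± SE. Where a class had no count, the fold was taken against a floor of 3 counts over the class; where it had 1 to 3 counts, the ratio has a 95% counting interval.

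Gene lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over all 63 pairs of list and contrast. Beside it stand camera with an estimated correlation and fry. For some lists the estimated correlation was below the preset one, as for VEGF genes between arterial-like and capillary-like cells (−0.0548). A larger p with the estimate does not come from a higher correlation there. Fry asks whether the genes of a list move on balance in a single direction, and its mixed test whether they move in either, neither of them comparing the list with other genes. The lists covered receptors of receptor-mediated uptake, the clathrin coat, caveolae, junctions, solute carriers, ABC transporters, leukocyte adhesion, antigen presentation, interferon response, Notch, Wnt, lysosome, immediate early genes, basement membrane, BMP and TGF-beta, VEGF, vascular tone, cholesterol, glycolysis, ribosomal proteins and mitochondrially encoded genes. The cell cycle list (4 of its 16 members in the table tested) and the sex-linked list (4 of 5) were too short for a list test. Genes were named by a fixed rule: 12 study genes, including Plvap, whatever their result; the 6 genes with the largest change in each direction among those past the threshold, with a mean log2 CPM of at least 5 and the same sign in all 3 sets; and up to 4 members of each list with the smallest adjusted p. Genes outside this rule are named as well: cell type and segment markers, further list members past the threshold, single genes compared between the sets, and genes chosen after their values were seen.

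The alternatives fixed beforehand were DESeq2 1.42.0 size factors and its Wald test, no filter and a stricter filter on low counts (a count in 20% of cells), no set term, cells thinned to 50000 counts, limma on mean log2(CPM + 1) over cells, clustering on variable genes, Leiden resolutions of 0.5 and 2, no cell filter and a stricter one (1000 genes and 100000 counts), leaving out each set in turn, and leaving out mural-high cells. After the data were seen, counting unnamed clusters as capillary-like and using the strongest arterial cluster alone were added. The count test was tested on simulated data: 3 runs per contrast on 9302 genes, 200 of them changed. Of genes changed 2-fold it called 2% between arterial-like and capillary-like sums, 2.67% between venous-like and capillary-like and 0.667% between arterial-like and venous-like sums. At 16-fold it called 56.7%, 62.7% and 57.3%, and it made 5, 8 and 9 false calls over all runs. Lists of 25 genes lowered 2-fold had an unadjusted camera p under 0.05 in 10 of 10 runs for each contrast, and unchanged lists in 1, 0 and 1 of 10. Genes were simulated independently and p was not adjusted over pairs of list and contrast. These runs therefore do not give the error rate of the list tests reported here. Figures were drawn with matplotlib 3.10.9.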

Results

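The series addresses how proteins carried in the blood enter the brain and how this changes with age. Its samples here were 745 single brain endothelial cells from 3-month-old mice, all labelled young, so no ages were compared. The cells came in 3 sets named in their titles: Young1 with 30.2% of the cells, Young2 with 34.6% and AY_Y3 with 35.2%. Read counts per cell had medians of 757949, 713031 and 411397 in these sets, and the cells together held 525469063 counts. A cell had a median of 2099, 2212.5 and 2257 genes with a count in Young1, Young2 and AY_Y3, and of 1567, 1698.5 and 1850.5 once thinned to 50000 counts. With a single age and no treatment, the comparison that the design allows is between vessel segments: arterial, capillary and venous endothelium.

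Endothelial transcripts dominated the data. Among all cells, 26 (3.49%, exact 95% interval 2.29 to 5.07) formed a cluster with 5 astrocyte markers raised, led by genes such as Aldoc, Slc1a2 and Slc1a3. Another 26 formed a cluster with all 10 pericyte markers raised, among them Kcnj8, Vtn and Pdgfrb. Both were left out, which kept 693 endothelial cells. Clusters with 18.5% and 9.24% of these were called arterial-like, with 11 and 14 of 16 arterial markers raised (Bmx, Vegfc, Gkn3 and others). A cluster with 18.3% was called venous-like, with 10 of 16 venous markers raised (Nr2f2, Slc38a5, Il1r1 and others) and 3 of 9 capillary markers. A cluster with 14.9% and another of 97 cells were called capillary-like, with 3 and 6 capillary markers raised (Rgcc, Cxcl12 and others) beside 1 and 7 venous markers. The last 4 clusters, with 8.37%, 7.65%, 6.06% and 3.03% of the cells, stayed unnamed. In that order they had 2, 2, 4 and 4 of 9 capillary markers raised. Venous markers raised were 2, 0, 2 and 0, and arterial ones 0, 0, 0 and 2. The first 2 had fewer than the 3 raised markers a name needed. The other 2 had a venous (Ephb4) or arterial (Mecom) marker among the top 10 genes by fold and no capillary one. Summed capillary markers had means over the sets of 17401 CPM in unnamed, 19922 in capillary-like, 17336 in venous-like and 8032 in arterial-like cells. In that order Itm2a alone was at 9991, 10795, 12284 and 4547 CPM. Rgcc, Cxcl12, Spock2, Ivns1abp and Hmcn1 were highest in capillary-like cells. Tgfb2 was highest in arterial-like cells, and Chn2, Itm2a and, by a small margin, Car4 in venous-like cells.

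Arterial-like cells made up 27.7% of the endothelial cells (exact 95% interval 24.4 to 31.2), capillary-like cells 28.9% (25.5 to 32.4) and venous-like cells 18.3% (15.5 to 21.4). The unnamed clusters held 25.1% (21.9 to 28.5). The arterial-like share was 26.4%, 30.7% and 25.9% in Young1, Young2 and AY_Y3, and the capillary-like share 27.4%, 26.9% and 32.1%. The venous-like share was 18.4%, 18.1% and 18.5%, and the unnamed share 27.8%, 24.4% and 23.5%. These are shares of cells that passed a sort for endothelium, not of the vessels in the brain. The shares depended on the clustering: at a Leiden resolution of 0.5 capillary-like cells were 47.9% and none stayed unnamed, and at 2 the unnamed share was 35.8%.

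**Figure D1:**
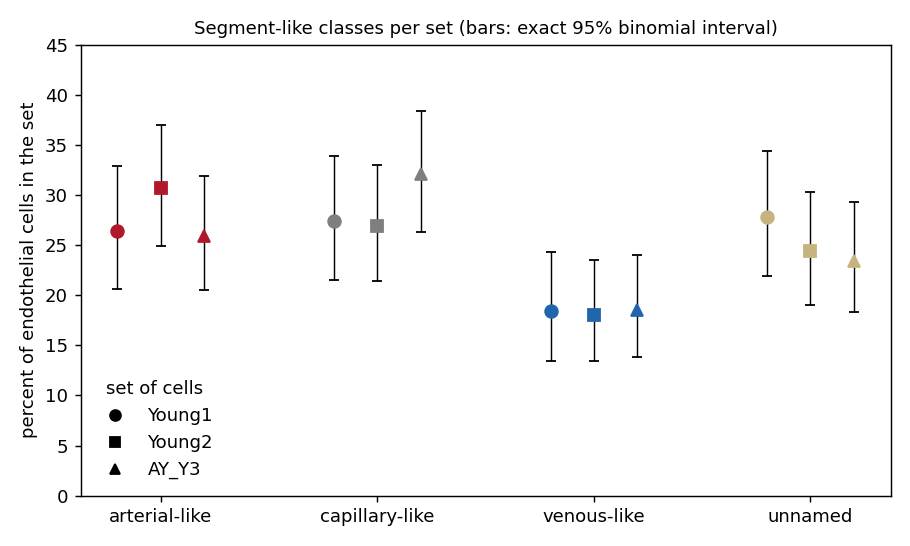
Share of endothelial cells per segment-like class (y axis, percent) in each of the 3 sets, with exact 95% binomial intervals that cover counting error only. Venous-like shares lie between 18.1% and 18.5%, and arterial-like shares between 25.9% and 30.7%.

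Markers of other cell types were low in all 3 classes but did not lie at the same level. Pericyte markers summed to 270 ± 157.8 CPM in arterial-like, 540 ± 154.97 in capillary-like and 394 ± 0.516 in venous-like cells (mean ± SD of 3 sets, here and in what follows). In the pericyte-like cells left out they summed to 23035 CPM. Smooth muscle markers summed to 293 ± 143.4, 62.1 ± 11.3 and 243.5 ± 368 CPM. Of these, Mylk, the myosin light chain kinase gene, was at 148.9 ± 14.2, 12.6 ± 7.13 and 30.3 ± 35.5 CPM. Astrocyte markers were at 46.1 ± 18.9, 67.5 ± 89.5 and 83.7 ± 77.1 CPM and oligodendrocyte markers at 159.5 ± 135.5, 99.2 ± 72.9 and 134.15 ± 132.9 CPM. Neuron markers were at 372 ± 63.7, 12.96 ± 13.7 and 12.5 ± 8.29 CPM, nearly all of it Stmn2 in arterial-like cells. Without that gene they were at 2.93 ± 3.37, 7.55 ± 7.53 and 11.02 ± 8.51 CPM.

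Further cell types were close to absent. Microglia or macrophage markers reached at most 12.6 ± 4.44 CPM (venous-like) and choroid plexus or ependymal markers 2.87 ± 3.81 CPM (capillary-like). Erythroid markers reached 0.511 ± 0.885 CPM (arterial-like), and fibroblast and lymphatic endothelial markers 0.360 ± 0.512 and 0.275 ± 0.476 CPM (both capillary-like). Markers of T cells, NK cells or neutrophils reached 0.0331 ± 0.0289 CPM (venous-like). The general endothelial markers were at 31400 ± 1682, 31312 ± 1493 and 28461 ± 1835 CPM in arterial-like, capillary-like and venous-like cells. Median genes per cell, thinned, were 1770, 1564 and 2306.

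Tfrc, Pglyrp1, Mfsd2a and Slc16a1 were lower in arterial-like than in capillary-like cells. Tfrc, the transferrin receptor gene, was at 42.9 ± 11.9 CPM in arterial-like and 261.3 ± 74.1 CPM in capillary-like cells (n = 3 sets), a log2 fold change of −2.60 ± 0.37 (edgeR adjusted p = 0.0205). Pglyrp1, which encodes a peptidoglycan recognition protein, was at 500.2 ± 137.4 against 2011 ± 151.6 CPM (−2.03 ± 0.21, edgeR adjusted p = 0.00891). Mfsd2a, a lysolipid transporter gene known to restrain caveolar vesicles, was at 253.95 ± 33.9 against 759 ± 182.5 CPM (−1.57 ± 0.18, edgeR adjusted p = 0.0109). Slc16a1, a monocarboxylate transporter gene, was at 46.6 ± 23.4 against 511 ± 44.8 CPM (−3.51 ± 0.40, edgeR adjusted p = 0.00964). Slc6a6, the taurine transporter gene, was higher in arterial-like cells, at 5307 ± 442 against 2351 ± 285 CPM (1.19 ± 0.13, edgeR adjusted p = 0.00961). Without Young2 and without AY_Y3 the edgeR adjusted p was 0.234 and 0.199 for Tfrc (6.24e-11 to 0.234 over the alternatives). In that order it was 0.117 and 0.0802 for Pglyrp1 (6.95e-24 to 0.117) and 0.142 and 0.238 for Mfsd2a (1.22e-12 to 0.238). Each gene called in this contrast moved the same way in 3 of 3 sets.

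In all, edgeR's quasi-likelihood test called 1.13% of 9302 genes between arterial-like and capillary-like cells, 43 higher and 62 lower. At an unadjusted p under 0.05 there were 913, where chance gives 465. Among the genes with the largest rise, Nov, of the CCN family of matricellular proteins, was at 329 ± 131.5 CPM in arterial-like cells and had no count in capillary-like cells. That is at least 14990-fold higher against a floor of 3 counts over the class (edgeR adjusted p = 0.0254). Pi16, a peptidase inhibitor gene, and Fhl1, which encodes a LIM domain protein, likewise had no count in capillary-like cells. They were at least 9562-fold and 6224-fold higher (edgeR adjusted p = 0.00891 and 0.0133). Nos1, encoding the neuronal form of nitric oxide synthase, was at 178.1 ± 74.5 against 0.253 ± 0.415 CPM (edgeR adjusted p = 0.0324). Stmn2, of the microtubule-binding stathmin family, was at 377 ± 73.6 against 5.60 ± 6.39 CPM and the cyclin gene Ccnd2 at 535 ± 69.2 against 35.7 ± 24.9 CPM (edgeR adjusted p = 0.0254 and 0.0195).

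The genes with the largest fall were led by Abcg1, a sterol exporter gene (2.02 ± 2.17 against 119.9 ± 10.9 CPM, −6.43 ± 0.88). Next came the channel gene Ttyh2 (−3.80 ± 0.31), the carboxypeptidase gene Cpe (−3.71 ± 0.45), Slc16a1, the ribonuclease gene Rnase4 (−3.51 ± 0.43) and Slc16a9 (−3.40 ± 0.49). Their edgeR adjusted p ran from 0.00651 to 0.0218. Fewer genes were called whichever set was left out, which also leaves less to estimate the spread. Without Young1, Young2 or AY_Y3 the count was 41, 3 and 0, and 35, 2 and 0 of the genes called on all sets still passed. Those tested again all kept their direction. DESeq2 called 513 genes and edgeR with no filter on low counts 48. Limma on mean log2 values called 577, 422 of them higher, there against a median over all genes of 0.11 on the log2 scale.

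Several genes known for segment differences did not pass in this contrast. Alpl, the tissue-nonspecific alkaline phosphatase gene, was at 1461 ± 294 CPM in arterial-like and 220 ± 95.8 CPM in capillary-like cells (2.77 ± 0.69, edgeR adjusted p = 0.144, higher in 3 of 3 sets). Over the alternatives its adjusted p ran from 2.2e-06 to 0.645, past the threshold in 5 of 18. The von Willebrand factor gene Vwf was at 132.3 ± 56.7 against 127.15 ± 50.9 CPM (−0.05 ± 0.46, edgeR adjusted p = 0.992). The adhesion genes Vcam1 and Icam1 and the glycoprotein gene Lrg1 had edgeR adjusted p of 0.307, 0.771 and 0.999. Cav1, the caveolin gene, was at 863 ± 204.2 against 490 ± 88.2 CPM (0.81 ± 0.16, edgeR adjusted p = 0.0634; 0.000202 to 0.372 over the alternatives). Log2 fold changes were −0.26 ± 0.09 for the claudin gene Cldn5 and −0.20 ± 0.07 for the glucose transporter gene Slc2a1, both with edgeR adjusted p = 0.357.

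**Figure D2:**
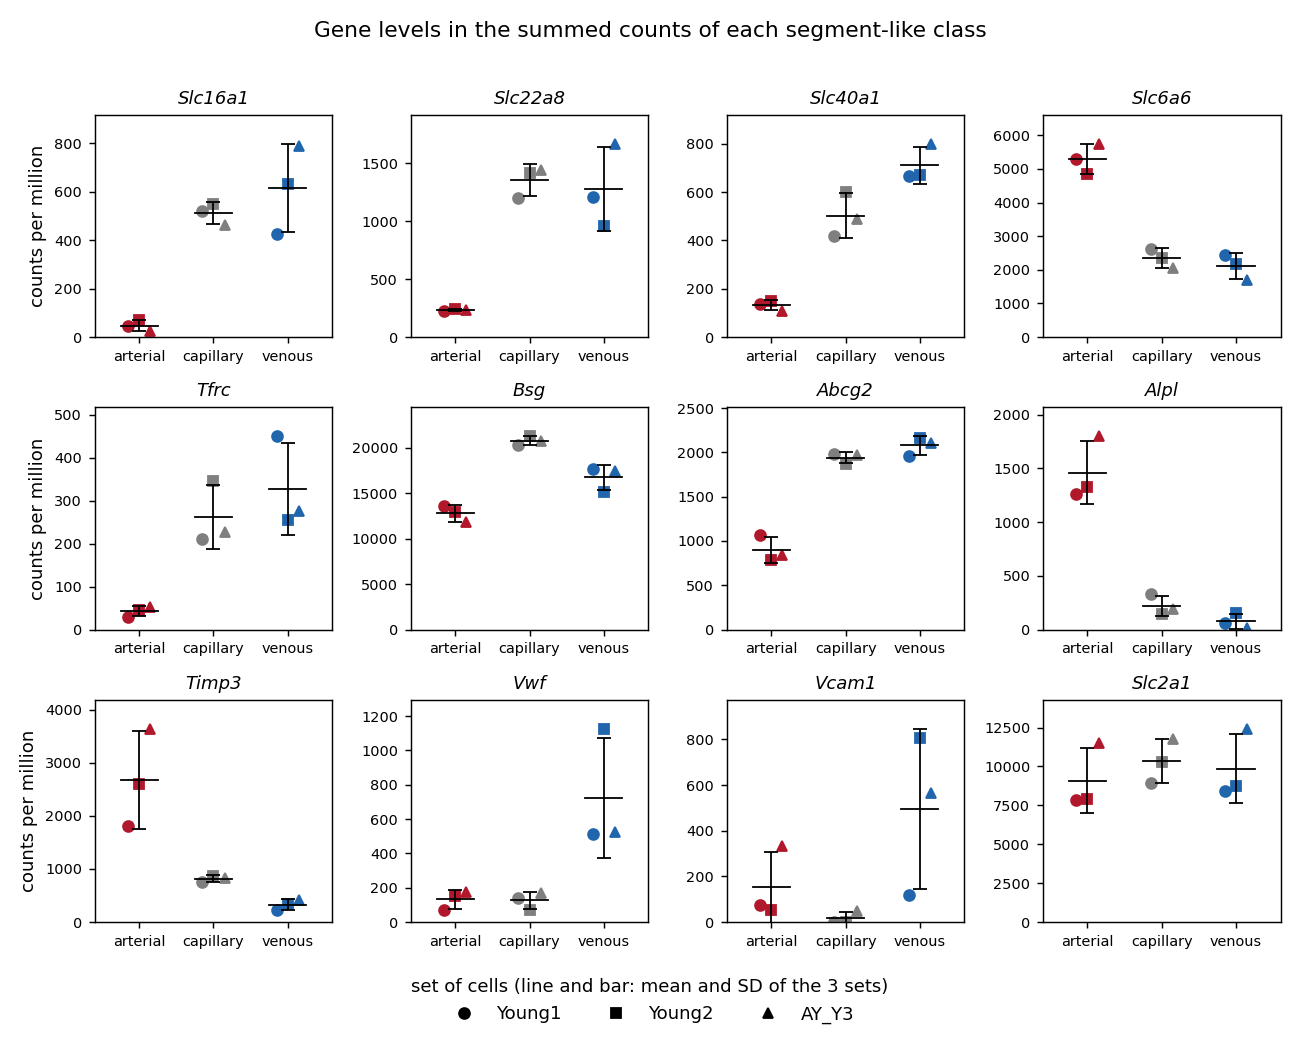
Level of 12 genes (y axis, CPM, linear scale) in arterial-like, capillary-like and venous-like cells, each point a set and each bar the mean ± SD of 3 sets. Slc16a1 had means of 46.6, 511 and 615 CPM in the 3 classes, Timp3 of 2682, 817 and 324 CPM, and Vwf of 132.3, 127.15 and 722 CPM.

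Solute carriers, receptors of receptor-mediated uptake and ABC transporters were lower as lists in arterial-like than in capillary-like cells by camera with a preset correlation. With an estimated correlation the ABC transporters did not pass. Of 18 receptors of receptor-mediated uptake, 6 were lower and 12 did not pass, and 10 were lower adjusted over the list alone. Their median was −0.87 (camera adjusted p = 5.21e-09, and adjusted p = 0.0499 with an estimated correlation). Among them were Bsg, a chaperone of monocarboxylate transporters (12795 ± 911 against 20764 ± 495 CPM, −0.70 ± 0.07, edgeR adjusted p = 0.00891), and the insulin-like growth factor receptor gene Igf1r (−1.24 ± 0.14, edgeR adjusted p = 0.00964). Fcgrt, the neonatal Fc receptor gene, was lower as well (−1.04 ± 0.14, edgeR adjusted p = 0.0179). Of 12 caveolae genes, Ehd2, an ATPase gene of the caveolar neck, was higher (1.64 ± 0.28, edgeR adjusted p = 0.0454) and Mfsd2a lower. Adjusted over the list alone, 6 caveolae genes were higher and 2 lower (median 0.84, camera adjusted p = 0.00223, but adjusted p = 0.136 with an estimated correlation). Smooth muscle markers, which moved with this and the other higher lists, stood at 293 ± 143.4 CPM in arterial-like and 62.1 ± 11.3 CPM in capillary-like cells.

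Of 29 tested solute carriers of the blood-brain barrier, 12 were lower, 1 higher and 16 did not pass, with a median log2 fold change of −1.20. Camera adjusted p = 1.61e-24, and adjusted p = 0.0499 with an estimated correlation. Adjusted over the list alone, 20 were lower and 1 higher. Beside Slc16a1, the organic anion transporter gene Slc22a8 was lower (−2.53 ± 0.18, edgeR adjusted p = 0.00493). So were the iron exporter gene Slc40a1 (−1.91 ± 0.19) and Slc3a2, the heavy chain of amino acid exchangers (−1.52 ± 0.15), both with edgeR adjusted p = 0.00891. Of 9 ABC transporters 2 were lower, the efflux pump gene Abcg2 (900 ± 146.1 against 1942 ± 58.9 CPM) and Abcg1, and 3 were lower adjusted over the list alone. Their median was −0.72 (camera adjusted p = 0.000132, but adjusted p = 0.136 with an estimated correlation). Pericyte markers, which moved with the lower lists, stood at 270 CPM in arterial-like and 540 CPM in capillary-like cells. With the cells highest in pericyte and smooth muscle markers left out, 90.5% of the genes called in this contrast still passed edgeR. The lists were not tested again without those cells.

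Lists outside transport passed camera between these classes as well. Of 28 interferon response genes Ifit3 was higher, and 3 were higher adjusted over the list alone (median 0.44, camera adjusted p = 0.000884, but adjusted p = 0.168 with an estimated correlation). Of 15 antigen presentation genes none passed, and 3 were higher adjusted over the list alone (median 0.44, camera adjusted p = 0.00612, but adjusted p = 0.218 with an estimated correlation). Of 13 VEGF, angiopoietin and sprouting genes none passed, and 6 were lower adjusted over the list alone (median −0.54, camera adjusted p = 0.000227, but adjusted p = 0.136 with an estimated correlation). Of 22 Wnt and barrier genes the Wnt inhibitor gene Apcdd1 was lower, and 3 were lower adjusted over the list alone (median −0.13, camera adjusted p = 0.0370, but adjusted p = 0.321 with an estimated correlation). Of 85 ribosomal protein genes none passed, also adjusted over the list alone (median −0.16, camera adjusted p = 0.00438, but adjusted p = 0.439 with an estimated correlation). Of 18 mitochondrially encoded genes mt-Rnr2 was lower, and 7 were lower adjusted over the list alone (median −0.31, camera adjusted p = 0.00378, but adjusted p = 0.330 with an estimated correlation).

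Several of these smaller list differences were also lost when a set was left out or the clustering was changed. Antigen presentation had camera adjusted p = 0.0908 without AY_Y3 (3.05e-05 to 0.218 over the alternatives). The Wnt list had 0.110 without Young1 and 0.0664 without Young2 (0.00418 to 0.321), and mitochondrially encoded genes 0.0664 without Young2 (0.00365 to 0.703). Clustered on variable genes, the interferon list had camera adjusted p = 0.321 (from 0.000793 up over the alternatives) and the ribosomal list 0.574 (from 0.00644 up). Mitochondrially encoded transcripts made up 30103 ± 2037 CPM in arterial-like and 37206 ± 3525 CPM in capillary-like cells.

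The remaining lists did not pass between arterial-like and capillary-like cells. Camera adjusted p was 0.0691 for immediate early genes (0.0284 without Young2; 0.0284 to 0.396 over the alternatives), 0.0814 for the lysosome and 0.202 for Notch signalling. It was 0.706 for vascular tone, 0.729 for BMP and TGF-beta, 0.749 for junctions and 0.905 for cholesterol. It was 0.949 for the clathrin coat, 0.971 for both leukocyte adhesion and glycolysis, and 0.972 for basement membrane and matrix. Medians and means had opposite signs for junctions (−0.16 and 0.06, test down), basement membrane (−0.15 and 0.39, test down) and glycolysis (−0.05 and 0.24). Cholesterol genes had a median of 0.33 and a mean of 0.11 beside a test pointing down.

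Single members of these lists passed. The junction gene Esam was lower (−0.52 ± 0.08, edgeR adjusted p = 0.0234), and Jag1, a Notch ligand gene, was higher (361 ± 23.7 against 113.4 ± 28.1 CPM, 1.71 ± 0.25, edgeR adjusted p = 0.0234). The immediate early gene Ier3 was lower (−1.73 ± 0.29, edgeR adjusted p = 0.0375). Of 19 basement membrane genes the metalloproteinase inhibitor gene Timp3 (1.65 ± 0.17) and Mmrn2 (1.48 ± 0.20) were higher, and Sparc (−0.74 ± 0.12) and Sparcl1 (−0.97 ± 0.17) lower. Of these 4 were higher and 3 lower adjusted over the list alone. Ltbp1, of the BMP and TGF-beta list, had 5101 counts against 1, a ratio of 4714 (95% counting interval 846 to 186200), and did not pass (edgeR adjusted p = 0.0655). The lipid transfer gene Pltp was lower (−0.80 ± 0.07, edgeR adjusted p = 0.00651).

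Between venous-like and capillary-like cells no gene passed the test. The capillary-like class included a cluster of 97 cells with 7 venous beside 6 capillary markers raised. Whether this mix narrowed the contrast was not tested. Of 19 tested genes of leukocyte adhesion and vessel inflammation, 10 had higher and 9 lower means in venous-like cells. Vwf was at 722 ± 350 CPM in venous-like and 127.15 ± 50.9 CPM in capillary-like cells (n = 3 sets; 2.44 ± 0.49, edgeR adjusted p = 0.257; 4.71e-07 to 0.884 over the alternatives). Vcam1 was at 497 ± 350 against 16.4 ± 27.8 CPM (edgeR adjusted p = 0.487; 6.36e-05 to 0.9999 over the alternatives). Lrg1 was at 200.4 ± 105.2 against 0.892 ± 1.54 CPM and Icam1 at 97.1 ± 48.5 against 35.9 ± 35.5 CPM (edgeR adjusted p = 0.676 and 0.868). Each of these 4 was higher in 3 of 3 sets. Alpl was at 75.5 ± 69.2 against 220 ± 95.8 CPM (edgeR adjusted p = 0.691) and Mfsd2a at 488 ± 154.3 against 759 ± 182.5 CPM (edgeR adjusted p = 0.538). Tfrc was at 327 ± 106.4 against 261.3 ± 74.1 CPM (0.35 ± 0.35, edgeR adjusted p = 0.915). Pglyrp1, Cav1, Cldn5 and Slc2a1 had log2 fold changes of −0.25, 0.36, 0.04 and −0.08 (edgeR adjusted p = 0.884, 0.741, 0.97495 and 0.890).

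edgeR's quasi-likelihood test called 0 of 9302 genes between venous-like and capillary-like cells, with a smallest adjusted p of 0.0583. At an unadjusted p under 0.05 there were 623 genes, 364 of them lower, where chance gives 465. DESeq2 called 1.95% of the genes, 74 of them higher. Limma on mean log2 values called 1700, 1681 of them higher, against a median over all genes of 0.39 on that scale and with 2306 against 1564 thinned genes per cell. edgeR called 2 without the set term, 7 with a stricter filter, 19 on thinned cells, 5 at a Leiden resolution of 0.5 and 1 with unnamed clusters counted as capillary-like. Igf1r had a log2 fold change of −0.71 ± 0.14 (edgeR adjusted p = 0.257), the glutamate transporter gene Slc1a1 −1.07 ± 0.25 (edgeR adjusted p = 0.421) and Slc40a1 0.52 ± 0.19 (edgeR adjusted p = 0.624). Hey1, a Notch target gene, was at 1.01 ± 1.76 against 48.7 ± 27.5 CPM and the nuclear receptor gene Nr4a1 at 18.8 ± 27.4 against 204.7 ± 131.9 CPM (edgeR adjusted p = 0.414 and 0.222). Timp3 had −1.40 ± 0.17 and the endoglin gene Eng −0.64 ± 0.13 (edgeR adjusted p = 0.0894 and 0.258).

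Of the lists, 19 tested leukocyte adhesion genes had a median log2 fold change of 0.33 in venous-like against capillary-like cells, with none past and 2 higher adjusted over the list alone. Camera adjusted p = 0.0199, but adjusted p = 0.301 with an estimated correlation. Lower medians came from Notch signalling (−0.38, camera adjusted p = 0.0151, but adjusted p = 0.184 with an estimated correlation) and basement membrane (−0.40, camera adjusted p = 0.0149, but adjusted p = 0.184 with an estimated correlation). BMP and TGF-beta genes had −0.33 (camera adjusted p = 0.0368, but adjusted p = 0.240 with an estimated correlation) and VEGF, angiopoietin and sprouting genes −0.35 (camera adjusted p = 0.00115, but adjusted p = 0.136 with an estimated correlation). Vascular tone genes had −0.51 (camera adjusted p = 0.0184, but adjusted p = 0.184 with an estimated correlation). Adjusted over the list alone, 2 basement membrane genes were lower and 1 higher, and 1 gene each of Notch, tone and BMP was lower. Ribosomal protein genes had a median of 0.16 (camera adjusted p = 0.00793, but adjusted p = 0.451 with an estimated correlation), with none higher adjusted over the list alone. Mitochondrially encoded genes had 0.27 (camera adjusted p = 0.00445, but adjusted p = 0.338 with an estimated correlation), with 4 higher adjusted over the list alone.

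Most of these list results were lost on leaving out a set. Leukocyte adhesion had camera adjusted p = 0.217 without Young2 (0.000117 to 0.301 over the alternatives), ribosomal proteins 0.335 without Young2 (4.02e-06 to 0.451) and vascular tone 0.183 without AY_Y3 (0.00955 to 0.184). Notch had 0.0678 without Young1 and 0.0664 without Young2 (0.00173 to 0.184). Basement membrane had 0.0678 without Young1 and 0.0830 without AY_Y3 (0.0164 to 0.184). BMP had 0.427 without Young1 and 0.0647 without Young2 (0.00482 to 0.427), and mitochondrially encoded genes 0.0593 without Young1 (0.000213 to 0.338). Clustered on variable genes, the VEGF list had camera adjusted p = 0.130 (2.29e-06 to 0.136 over the alternatives). Beside these lists, smooth muscle markers stood at 243.5 ± 368 CPM in venous-like and 62.1 ± 11.3 CPM in capillary-like cells, and microglia or macrophage markers at 12.6 ± 4.44 and 7.38 ± 10.7 CPM. Mitochondrially encoded transcripts summed to 44737 ± 4408 and 37206 ± 3525 CPM, and ribosomal protein transcripts to 22325 ± 1344 and 19457 ± 860 CPM.

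Lists of transport across the barrier did not pass between venous-like and capillary-like cells. Receptors of receptor-mediated uptake had a median of −0.11 with a mean of 0.02 (camera adjusted p = 0.241, 3 lower adjusted over the list alone). Caveolae had 0.12 (camera adjusted p = 0.415; 0.0229 without Young1, and 0.0229 to 0.906 over the alternatives). Solute carriers had −0.11 (camera adjusted p = 0.20) and ABC transporters 0.10 with a mean of −0.15 (camera adjusted p = 0.971). For immediate early genes camera adjusted p was 0.0965 (0.0323 without Young2; 0.0021 to 0.536 over the alternatives). It was 0.122 for antigen presentation, 0.593 for junctions, 0.612 for the clathrin coat, 0.625 for cholesterol, 0.729 for the lysosome and 0.850 for the interferon response. For Wnt it was 0.892, with a median of −0.09 and a mean of 0.15, and for glycolysis 0.247, with a median of −0.08 and a mean of 0.02.

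With edgeR on all sets, the contrast of arterial-like and venous-like cells had the most called genes. Alpl was at 1461 ± 294 CPM in arterial-like and 75.5 ± 69.2 CPM in venous-like cells (n = 3 sets; 4.54 ± 0.76, edgeR adjusted p = 0.0278). Tfrc was lower in arterial-like cells, at 42.9 ± 11.9 against 327 ± 106.4 CPM (−2.95 ± 0.38, edgeR adjusted p = 0.0098), as was Pglyrp1 (−1.77 ± 0.21, edgeR adjusted p = 0.0079). Hey1 was at 367.5 ± 42.1 against 1.01 ± 1.76 CPM (9.98 ± 1.74, edgeR adjusted p = 0.0321), and Slc16a1 at 46.6 ± 23.4 against 615 ± 182.1 CPM (−3.79 ± 0.41, edgeR adjusted p = 0.0064). Fn1, the fibronectin gene, was at 616 ± 158.9 against 1788 ± 230.4 CPM (−1.55 ± 0.17, edgeR adjusted p = 0.0066). Timp3 was at 2682 ± 920 against 324 ± 102.7 CPM (3.04 ± 0.18, edgeR adjusted p = 0.0022). Without Young1, Young2 and AY_Y3 the edgeR adjusted p of Alpl was 0.1503, 0.0642 and 0.181 (9.78e-08 to 0.181 over the alternatives). Without Young2 and without AY_Y3 it was 0.102 and 0.132 for Tfrc (3.31e-14 to 0.132) and 0.0839 and 0.0572 for Pglyrp1 (1.67e-18 to 0.0839). Each gene called in this contrast moved the same way in 3 of 3 sets.

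edgeR's quasi-likelihood test called 1.84% of 9302 genes between arterial-like and venous-like cells, 88 higher and 83 lower, and 1090 had an unadjusted p under 0.05, where chance gives 465. Cdh13, encoding the anchored cadherin T-cadherin, was at 603 ± 94.97 CPM in arterial-like cells and had no count in venous-like cells. That is at least 19270-fold higher against a floor of 3 counts over the class (edgeR adjusted p = 0.0405). Pi16 had 31041 counts against 1, a ratio of 22190 (95% counting interval 3982 to 876400). Fhl1 was at 151.65 ± 29.1 against 0.0771 ± 0.0931 CPM, Nov at 329 ± 131.5 against 0.567 ± 0.983 CPM and Lypd1 at 169.45 ± 18.8 against 0.737 ± 0.966 CPM (edgeR adjusted p = 0.0136, 0.0303 and 0.0187). The largest falls were in the monooxygenase gene Fmo2 (1.28 ± 2.21 against 211.6 ± 71.99 CPM), the adhesion gene Flrt2 (4.08 ± 5.82 against 208.9 ± 110.5 CPM), Abcg1 (−5.82 ± 0.85), the secreted factor gene Ndnf (12.1 ± 7.29 against 426 ± 44.4 CPM), Rnase4 (−3.95 ± 0.44) and Slc16a1. Their edgeR adjusted p ran from 0.0064 to 0.0474.

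Vwf and Mfsd2a did not pass between arterial-like and venous-like cells (−2.49 ± 0.48 and −0.90 ± 0.18, edgeR adjusted p = 0.0507 and 0.0545). Over the alternatives their adjusted p ran from 2.76e-08 to 0.262 and from 0.000295 to 0.499. Vcam1, Lrg1, Icam1, Cav1, Cldn5 and Slc2a1 did not pass either (edgeR adjusted p = 0.695, 0.360, 0.381, 0.303, 0.197 and 0.617). Without Young1, Young2 or AY_Y3 the count of called genes was 76, 3 and 17, and 65, 3 and 16 of those called on all sets still passed, each in its direction. DESeq2 called 659 genes and edgeR with no filter on low counts 95. Limma on mean log2 values called 1424, with 326 of them higher, there against a median over all genes of −0.25 on the log2 scale.

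Lists of receptors, solute carriers and ABC transporters were lower in arterial-like than in venous-like cells by camera with a preset correlation. Of these, only the solute carriers passed with an estimated correlation, and caveolae was not lower. Of 18 receptors of receptor-mediated uptake Tfrc and Bsg were lower, and 10 were lower adjusted over the list alone (median −0.56, camera adjusted p = 1.97e-06, but adjusted p = 0.0766 with an estimated correlation). Of 29 solute carriers 12 were lower, Slc6a6 was higher (1.35 ± 0.13) and 16 did not pass, with 15 lower and 2 higher adjusted over the list alone. Their median was −1.25 (camera adjusted p = 2.97e-18, and adjusted p = 0.0499 with an estimated correlation). Slc22a8 (−2.43 ± 0.18) and Slc40a1 (−2.43 ± 0.19) were among the lower ones, with edgeR adjusted p = 0.0026 and 0.0028. Of 9 ABC transporters 3 were lower, Abcg2 (−1.22 ± 0.12), Abcg1 and the efflux pump gene Abcb1a (451 ± 103.1 against 852 ± 45.4 CPM), and 3 also adjusted over the list alone. Their median was −0.94 (camera adjusted p = 0.000212, but adjusted p = 0.136 with an estimated correlation). Moving with these lists, pericyte markers stood at 270 ± 157.8 and 394 ± 0.516 CPM in arterial-like and venous-like cells, and microglia or macrophage markers at 0.922 ± 0.342 and 12.6 ± 4.44 CPM. Without the cells highest in pericyte and smooth muscle markers, 90.1% of the genes called in this contrast still passed edgeR.

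Ribosomal protein genes (85; none past) had a median of −0.31 in arterial-like against venous-like cells (camera adjusted p = 9.36e-07, but adjusted p = 0.259 with an estimated correlation). Of 18 mitochondrially encoded genes 6 were lower, such as mt-Rnr2 (−0.54 ± 0.05), and 9 adjusted over the list alone (median −0.62, camera adjusted p = 6.75e-07, but adjusted p = 0.185 with an estimated correlation). With the strongest arterial cluster alone the ribosomal list had camera adjusted p = 0.529 (2.02e-06 to 0.529 over the alternatives). Thinned genes per cell were 1770 in arterial-like and 2306 in venous-like cells, and mitochondrially encoded transcripts 30103 ± 2037 and 44737 ± 4408 CPM.

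Notch, tone and matrix genes included members that were higher in arterial-like than in venous-like cells. Of 15 Notch genes 3 were higher, Hey1, Jag1 (361 ± 23.7 against 122.75 ± 31.6 CPM) and the hypoxia-linked transcription factor gene Epas1 (0.64 ± 0.09). There were 5 Notch genes higher and 1 lower adjusted over the list alone (median 0.64, camera adjusted p = 0.00277, but adjusted p = 0.136 with an estimated correlation). Of 22 Wnt genes Apcdd1 (−2.32 ± 0.36) and Lef1 (−1.30 ± 0.24) were lower and Sox18 (0.81 ± 0.15) higher. Of the Wnt genes 4 were lower and 1 higher adjusted over the list alone (median −0.28, camera adjusted p = 0.0370, but adjusted p = 0.323 with an estimated correlation). Of 23 immediate early genes Nr4a1 (793 ± 381 against 18.8 ± 27.4 CPM) and the heat shock gene Hspa1a (1.11 ± 0.18) were higher. Adjusted over the list alone, 4 immediate early genes were higher and 1 lower (median 0.45, camera adjusted p = 0.00445, but adjusted p = 0.240 with an estimated correlation).

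Of 19 basement membrane genes Timp3, Mmrn2, Ltbp4 and Adamts1 were higher and Fn1 and Sparc lower, also adjusted over the list alone, with a median of −0.06 beside a mean of 0.57 (camera adjusted p = 0.130). Eng, of the BMP and TGF-beta list, was higher (0.81 ± 0.13), and 3 genes of that list were higher adjusted over the list alone (median 0.33, camera adjusted p = 0.0298, but adjusted p = 0.240 with an estimated correlation). Of 16 vascular tone genes the endothelin gene Edn1 (648 ± 190.4 against 161.3 ± 79.7 CPM) and the sphingolipid receptor gene S1pr1 (0.98 ± 0.13) were higher. Adjusted over the list alone, 2 tone genes were higher and 1 lower (median 0.82, camera adjusted p = 0.0368, but adjusted p = 0.202 with an estimated correlation). Smooth muscle markers stood at 293 ± 143.4 and 243.5 ± 368 CPM in arterial-like and venous-like cells. Without Young1, camera adjusted p was 0.0593 for immediate early genes (0.000444 to 0.240 over the alternatives) and 0.171 for Wnt (0.00545 to 0.323). It was 0.236 for BMP (0.0153 to 0.240) and 0.0584 for tone (0.0114 to 0.202).

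Further lists between arterial-like and venous-like cells had few or no called genes. Caveolae had a median of 0.62, with none past and 5 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0309, but adjusted p = 0.202 with an estimated correlation). Without Young1 and without Young2 the camera adjusted p of caveolae was 0.104 and 0.0675 (0.00704 to 0.202 over the alternatives). Junctions had a median of 0.16 (camera adjusted p = 0.923), where Pecam1 was higher (0.74 ± 0.12) and Esam (−0.42 ± 0.08) and Tjp1 (−1.08 ± 0.20) lower. Leukocyte adhesion had a median of −0.52 (camera adjusted p = 0.0505; 0.0143 without Young1 and 0.0135 without AY_Y3, and 0.0135 to 0.588 over the alternatives). The interferon response had a median of 0.58, with no gene past and 7 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000722, but adjusted p = 0.164 with an estimated correlation). The lysosome had a median of 0.26 with none past (camera adjusted p = 0.0397, but adjusted p = 0.202 with an estimated correlation). Without Young1, Young2 and AY_Y3 the lysosome had camera adjusted p = 0.0744, 0.127 and 0.0551 (0.0025 to 0.202 over the alternatives). Camera adjusted p was 0.247 for antigen presentation, 0.355 for VEGF, 0.452 for glycolysis, 0.577 for cholesterol and 0.614 for the clathrin coat.

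**Figure D3:**
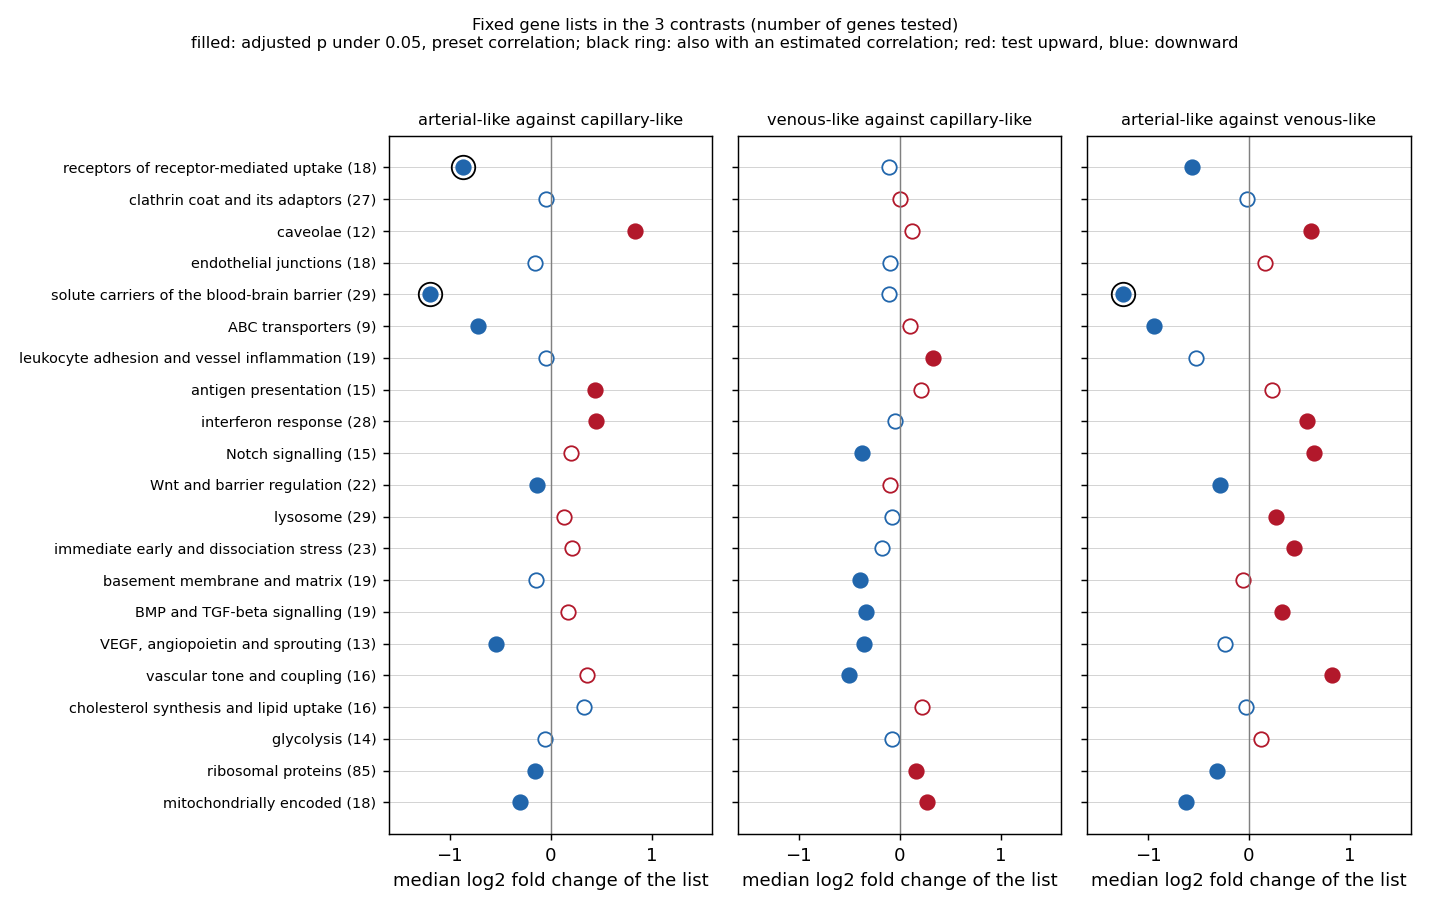
Median log2 fold change of 21 gene lists (rows) in the 3 contrasts (x axis), filled where camera with a preset correlation passed and ringed in black where camera with an estimated correlation also passed. The solute carriers had medians of −1.20, −0.11 and −1.25 in arterial-like against capillary-like, venous-like against capillary-like and arterial-like against venous-like cells.

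In all, 31 of the 63 pairs of list and contrast passed camera with a preset correlation. With an estimated correlation 3 did: arterial-like cells' solute carriers against capillary-like and against venous-like cells, and their receptors against capillary-like cells. Fry, which asks for movement in a single direction, passed 27 pairs, and its mixed test 57. Cell cycle transcripts were low, at 263 ± 83.8, 195.9 ± 22.04 and 210 ± 101.4 CPM in arterial-like, capillary-like and venous-like cells. Neither the 4 tested cell cycle genes (Mcm2, Mcm3, Mcm6 and Pcna) nor the 4 tested sex-linked genes passed in any contrast.

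The arterial differences from capillary-like and from venous-like cells shared many genes. Of the genes higher in arterial-like cells, 29 were called in both contrasts (of 43 and 88), and of the genes lower 48 (of 62 and 83). The lower ones included Tfrc, Slc16a1, Slc22a8, Slc40a1, Pglyrp1, Abcg1, Abcg2 and Bsg. Independent lists of these sizes would share 0.407 and 0.553 genes. Part of the excess may come from the shared arterial-like sums.

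The sets of cells were described and not tested, since the labels give no condition that differs between them. Immediate early and stress genes summed to 9836 CPM in Young1, 6435 in Young2 and 4751 in AY_Y3, the highest 2.07 times the lowest (1.97 with cells thinned to equal depth), and Fos was at 525, 163.65 and 67.6 CPM. The ribosomal RNA symbol Rn18s-rs5 was at 34531, 36663 and 59297 CPM. The other lists differed by 1.02 (ribosomal proteins) to 1.32 times (antigen presentation) between the highest and the lowest set, and solute carriers were at 21354, 22318 and 25327 CPM. Of the sex-linked genes, Xist had 0, 0 and 1 count in the sets, and a Y-linked gene had counts in 49.8%, 53.9% and 50.4% of the cells.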

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

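The tests of sequencing depth, of an arterial cell in the well, of a pericyte or a whole astrocyte beside an endothelial cell, and of Mylk in cells without other smooth muscle markers were chosen only after the result was seen. No biological explanation was tested for any of the patterns, since the design gives no group to set against them.

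The cells left out of every comparison carried markers of other cell types. Pericyte markers summed to 23035.0 CPM in the 26 pericyte-like cells (95% counting interval 22968 to 23102), against 437 CPM in the endothelial cells. Vtn, Rgs5 and Kcnj8 were at 12349 ± 2139, 4945 ± 332 and 1728 ± 694 CPM, and were found in 6.64%, 28.3% and 1.01% of the endothelial cells as well. Astrocyte markers summed to 2929.4 CPM in the 26 astrocyte-like cells (2905 to 2954), against 61.6 CPM in the endothelial cells, with Aldoc in 57.7% and Slc1a2 in 69.2% of them and in 3.61% and 7.65% of the endothelial cells. Oligodendrocyte markers reached 5517.8 CPM in the same cells (5484 to 5551), with 7250 ± 12371 CPM over the sets, a spread that a high level in a single set gives. These values stand out because they come from cells that no comparison used. The FACS for endothelial cells should remove pericytes, astrocytes and oligodendrocytes, and its gate markers are not given in the sources used here.

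Both groups also carried endothelial transcripts. In the pericyte-like cells endothelial markers stood at 63.91% of their level in the endothelial cells, and thinned genes per cell at 1.32 times. A pericyte and an endothelial cell in 1 well is a candidate explanation that these values leave standing. In the astrocyte-like cells endothelial markers stood at 85.85% with 0.94 times the genes, which argues against a whole astrocyte in each of these wells. Both values were taken over the cells together and cannot exclude a whole astrocyte in some wells. These cells held 55.86% of all counts on astrocyte markers. Their cluster was named for raised astrocyte markers, so a large share is partly selected for. It cannot decide about free astrocyte RNA spread over all wells. A piece of an astrocyte attached to an endothelial cell was not tested.

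Venous-like cells had more genes with a count than capillary-like cells. Thinned to equal depth, the ratio was at least 1.405 in each set, which argues against deeper sequencing. Among cells with few counts on markers of other types it was at least 1.358, which argues against a cell of another type in the well, and among venous-like cells low in arterial markers at least 1.356, which argues against an arterial cell. Only 3 venous-like cells were low in both arterial and capillary markers, too few to test a capillary cell in the well. That, and a second cell of the same segment in the well, stay open.

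Arterial-like cells had more counts on smooth muscle markers than capillary-like cells. Of 6 such markers 2 (Acta2, at 68.4 ± 61.1 against 7.16 ± 12.4 CPM, and Mylk, at 148.88 ± 14.18 against 12.6 ± 7.13) were at 2 times the capillary-like level or more in each set, and 2 (Cnn1 and Myl9) were at or below it in 2 sets or more. Of the Mylk counts in arterial-like cells, 71.63% lay in cells without a count on Acta2, Tagln or Myh11, which were found in 13 arterial-like cells. Mylk had a count in 63 arterial-like cells, and 7 of these had a count on Acta2, Tagln or Myh11. Most arterial-like cells with Mylk thus showed none of these other markers. As Mylk is a single marker, these values do not decide whether smooth muscle cells shared wells with arterial cells.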

How the results depend on the processing

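Counting unnamed clusters as capillary-like, the strongest arterial cluster alone, and the other splits of the sums were chosen only after the result was seen. On all 3 sets 1.13% of tested genes passed between arterial-like and capillary-like cells, 0% between venous-like and capillary-like and 1.84% between arterial-like and venous-like cells. Every gene called on all sets that was tested again kept its direction under each alternative.

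In the order of these contrasts, the share was 5.51%, 1.95% and 7.08% with DESeq2, 3.08%, 0.242% and 4.25% on thinned cells, and 6.20%, 18.3% and 15.3% with limma on mean log2 values. With a stricter filter on low counts (4259 genes tested) it was 4.30%, 0.164% and 6.27%, and with none (19255 genes) 0.249% and 0.493% in the arterial contrasts. Leiden resolution 2 gave 0.638% and 1.07% there. Clustering on variable genes gave 2.20% between arterial-like and capillary-like cells. In that setting tested genes had also been used to define the classes, so a larger share is partly built in. At a resolution of 0.5, 0.0547% passed between venous-like and capillary-like cells. With unnamed clusters counted as capillary-like, 0.0110% passed there and 2.88% between arterial-like and venous-like cells. Leaving out 1 set gave 0% (without AY_Y3) to 0.441% (without Young1) between arterial-like and capillary-like cells, and 0.0322% (without Young2) to 0.818% (without Young1) between arterial-like and venous-like cells. With the set still a block, under the remaining settings the share was 1.12% to 1.53% between arterial-like and capillary-like cells, 0% between venous-like and capillary-like cells, and 1.63% to 2.62% between arterial-like and venous-like cells; having no cell filter removed no cell and tested nothing. Fewer genes tested change the adjustment by construction, and fewer sets leave less to estimate the spread; for the rest the cause was not tested.

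The set was a block in the fit, and the sums of a set share it by construction. With no replicate block 1.06%, 0.0215% and 1.75% of genes passed, and 26 pairs of list and contrast instead of 31. Of the genes called with the block between arterial-like and capillary-like cells 72.4% still passed without it, and 74.9% between arterial-like and venous-like cells. With the mean of each class over the sets taken out of log2 CPM, the deviations of the sums of a set correlated at 0.0234 to 0.0602 between classes.

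With limma on mean log2 values 73.1%, 98.9% and 22.9% of the called genes were higher, where edgeR on all sets gave 43 higher and 62 lower, none, and 88 higher and 83 lower, and it turned 4 genes between venous-like and capillary-like cells, to 1.5046 for Scarb1, 1.45 for Tie1, 1.21 for Pkm and 1.11 for Gpi1, where the median over all genes was 0.39. The ribosomal list between arterial-like and capillary-like cells had a median of −0.0385 beside a camera test pointing up with the strongest arterial cluster alone (adjusted p = 0.487, 0.00644 to 0.574 over the alternatives), where the median over all genes was −0.15; it was lower on all sets (−0.157). The cause was not tested. With an estimated correlation 3 pairs of list and contrast passed in camera, and 22 to 31 under the other alternatives.

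Class shares moved with the clustering. On variable genes the arterial-like, capillary-like, venous-like and unnamed shares were 22.37%, 35.79%, 24.96% and 16.88%. At a resolution of 0.5 the last 3 were 47.91%, 25.4% and 0.0%, and at 2 they were 23.23%, 12.41% and 35.79%. With stricter cells the capillary-like and unnamed shares were 23.47% and 29.45%. Thinned to equal depth, the highest set over the lowest was 1.181 for genes per cell, 1.034 for receptors, 1.08 for Notch, 1.462 for cell cycle and 1.008 for ribosomal proteins. The cause was not tested.

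With 3 sums against 3 there are 10 splits, too few for a share under 0.05. Between arterial-like and capillary-like cells 1 of 10 splits, the real one with 43 genes higher and 62 lower, gave as many, and the highest other gave 0. Between arterial-like and venous-like cells 1 of 10 did, the real one with 88 and 83, and the highest other gave 0. Between venous-like and capillary-like cells the real split gave 0 and the highest other 1, so that 10 of 10 had as many by construction and the count says nothing. In simulated sums 28.7% of genes changed 4-fold between arterial-like and capillary-like cells were called, so a gene that did not pass is not shown to be unchanged.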

Other observations

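Amd1, Azin1, Glul, Mt1, Mt2, Gatm and Slc31a1 were tested with all other genes and chosen only after their values were seen, and no list of their pathways was fixed or tested. Amd1, an S-adenosylmethionine decarboxylase gene, was at 331.6 ± 82.4 CPM in arterial-like cells against 51.7 ± 7.06 in capillary-like (2.67 ± 0.30, edgeR adjusted p = 0.00964) and 24.1 ± 2.70 in venous-like cells (3.77 ± 0.31, edgeR adjusted p = 0.00287). Azin1, an antizyme inhibitor gene, had log2 fold changes of 3.82 ± 0.38 and 3.39 ± 0.37 (edgeR adjusted p = 0.00891 and 0.0066). Glul, the glutamine synthetase gene, was higher as well, by 1.26 ± 0.16 and 2.17 ± 0.16 on the log2 scale (edgeR adjusted p = 0.0130 and 0.00261). Each was higher in 3 of 3 sets.

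Of single genes lower in arterial-like cells, the metallothionein gene Mt1 had log2 fold changes of −2.35 ± 0.24 against capillary-like and −2.75 ± 0.24 against venous-like cells (edgeR adjusted p = 0.00891 and 0.00287), and Mt2 of −2.36 ± 0.36 and −3.30 ± 0.38 (edgeR adjusted p = 0.0269 and 0.00694). Gatm, a gene of creatine synthesis, had −2.84 ± 0.21 and −2.89 ± 0.21 (edgeR adjusted p = 0.00493 and 0.00261), and the copper transporter gene Slc31a1 −1.53 ± 0.18 and −1.80 ± 0.18 (edgeR adjusted p = 0.0108 and 0.00473). Each was lower in 3 of 3 sets.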
